A study of Mus musculus with 6 samples.

How the data were processed

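The arrays measured total RNA of a mouse ILC2 line after CRISPR with a Myc guide or a non-targeting guide, 3 arrays per group. Groups were taken from the sample titles. Per the submitters' processing notes, the authors made the deposited log2 values with RMA, and limma 3.14.4 is named there too. RMA subtracts background, brings all arrays to the same distribution of intensities and summarises the probes of a probe set to 1 log2 value, so a value is relative to the other arrays and a shift of all transcripts together is removed. The array version, the probe set definition and the genome build are not given in the sources used here. Arrays carry no read depth; dim probe sets lie close to background, and the lower quartile of the arrays was 2.04 to 2.13.

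The table held 25206 probe sets, whose identifiers are gene numbers. An annotation table gave 1 gene symbol for 23185 of them, several for 0 and none for 2021, which are unnamed here. All 23185 were found by gene number in a RefSeq gene table for GRCm38.p6, used only for gene type, transcript length and neighbouring genes. No gene had more than 1 probe set, so the 23185 named probe sets were tested as genes, without a filter on level.

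Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, not robust) as the arrays labelled Myc knockout minus control, with no covariate. All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists, beside camera with an estimated correlation and fry, which asks whether a list's genes move one way without setting them against other genes. The lists held 598 entries, of which 556 were measured; the rest are not analysed here. Some genes stand in a pair of lists: Cdkn1a (CDK inhibitors and p53 targets), Il2ra (ILC2 identity and IL-2 response), Gzmb (IL-2 response and NK cells), Lta (IL-2 response and ILC3) and Ncr1 (NK cells and ILC3). Adjustment over a list alone used the p-values of its measured members. For Myc, an exact two-sided permutation test of 3 against 3 arrays was added.

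The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Myc; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, leaving out predicted genes and small noncoding RNAs by symbol; of each list the 2 members that rose and the 2 that fell with the smallest adjusted p, or else its member with the smallest p, given as a value; and Il5, Il13, Gata3, Odc1, Ldha, Ncl and Cdkn1a whatever their value. Scarna13 was named because its symbol is not among those the rule leaves out. Areg and Il1rl1 were in that rule and are not analysed here. Further members named as examples were chosen after their values were seen.

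The procedure was tested on simulated data: 20 sets of 23185 genes with 200 changed genes and spreads drawn from the fitted prior. The ribosome biogenesis list was also shifted by 0.2, and its members did not count as false calls. Genes were drawn independently, so the rates below do not cover correlation between genes or effects shared within an array. For this comparison of 3 against 3 arrays, 36.4% of changed genes were recovered at a log2 change of 0.5, 88.6% at 1 and 97.5% at 2, and 5.09% of all calls were false. Alternatives were a replicate block, other prior variances, array weights, median centring, cyclic loess, filters on dim genes, each array left out, all probe sets, stricter thresholds and other list tests. Restriction to protein-coding genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9.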

Results

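Group 2 innate lymphoid cells (ILC2s) are lymphocytes without rearranged antigen receptors that secrete type 2 cytokines such as IL-5 and IL-13. Here an ILC2 line from C57BL/6J mice was cultured with IL-2 and IL-33 at 10 ng/ml and transduced with a lentiviral CRISPR construct that carried GFP and a guide RNA, either directed at Myc or non-targeting. Cells positive for GFP were sorted on day 6, and their total RNA was measured on 6 Affymetrix arrays, 3 per group. The comparison asks which transcripts differ between the Myc knockout and the control cells. The labels do not say whether the 3 arrays of a group came from separate cultures or transductions, so p-values measure only the spread between these samples, which may be technical. Array medians lay between 3.27 and 3.34 on the log2 scale. The SD of the log2 differences between arrays over all probe sets averaged 0.206 among controls, 0.233 among the arrays labelled Myc knockout and 0.263 between groups. With 3 arrays per group, the number of arrays limits the precision. Values below are means ± SD of log2 RMA values (n = 3 arrays per group), and log2 differences, arrays labelled Myc knockout minus control, are given ± SE.

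Myc, the transcription factor gene targeted by the guide, was not lower in the arrays labelled Myc knockout. Its log2 value was 9.27, 9.33 and 9.39 in the controls and 9.55, 9.79 and 9.73 in the arrays labelled Myc knockout, which gave means of 9.33 ± 0.058 and 9.69 ± 0.12. All 3 values of the arrays labelled Myc knockout lay above all 3 control values, a 1.28-fold difference (95% confidence interval 1.12 to 1.46). The difference did not pass over all genes, with limma's adjusted p = 0.127. Myc was named before the data were examined, and its unadjusted p in limma was 0.00329. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Myc mRNA thus went against the label, although an insertion or deletion need not lower the mRNA, so the level is a weak check of the labels. The groups are named by their labels throughout, and every direction below rests on those labels.

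Cytokine genes were among those that rose most in the arrays labelled Myc knockout. Il9, which encodes a type 2 cytokine, rose 2.65-fold, from 6.07 ± 0.12 to 7.48 ± 0.23, and Lta, which encodes lymphotoxin alpha, rose 2.67-fold, from 5.76 ± 0.22 to 7.18 ± 0.051 (limma's adjusted p = 0.0205 and 0.0162). Hamp, the gene of the iron hormone hepcidin, rose from 3.30 ± 0.17 to 4.92 ± 0.12, the protease gene Adamts1 rose 2.58-fold, the proton pump subunit gene Atp6v0d2 2.88-fold and the enamel matrix gene Enam 2.31-fold. The T cell receptor gamma joining segments Trgj2 and Trgj1 rose 4.06-fold and 2.72-fold, and the small Cajal body RNA Scarna13 rose 2.20-fold. Among the genes that fell, the circadian repressor gene Bhlhe40 was 2.26-fold lower, Ddit4, an inhibitor of mTORC1 signalling, 2.00-fold, and Ankrd37 1.77-fold. Bhlhe41, also a circadian repressor gene, fell from 4.81 ± 0.32 to 3.57 ± 0.096, near the array medians. The heat shock gene Hspa1a fell from 4.93 ± 0.11 to 3.31 ± 0.41, near the array medians.

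In all, 59 genes rose and 46 fell among 23185 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and the smallest adjusted p was 0.0138. At an unadjusted p under 0.05 the counts were 1616 higher and 1834 lower. This balance depended on the scaling: median centring gave 1216 higher and 2227 lower at that p (61 and 61 past the threshold), and cyclic loess gave 1702 and 1583 (70 and 38 past the threshold). The groups did not overlap for 19.8% of genes, where chance gives 10% for 3 against 3. Protein-coding genes made up 40 of the genes that rose and 41 of those that fell. Small RNA genes accounted for 10 that rose and 0 that fell, and T cell receptor gamma segments for 5 that rose. Other genes that the selection rule named were Vmn1r103, Btbd35f6 and Cyp3a41b, which rose from 3.03 ± 0.48, 1.98 ± 0.30 and 3.03 ± 0.44 to 5.04 ± 0.30, 3.73 ± 0.34 and 4.77 ± 0.17, and Snx32, Bcar1 and Khnyn, which fell 1.69-fold, 1.63-fold and 1.58-fold. The control levels of Vmn1r103, Cyp3a41b and Hamp (3.30) were at or below the array medians and that of Btbd35f6 below the lower quartiles of 2.04 to 2.13, so no exact fold can be read from them. The values of Vmn1r103, Btbd35f6, Cyp3a41b, Hspa1a and the Trg segments are uncertain, since their families hold near-identical copies that a probe set can share. Without control replicate 1, 2 or 3, or without replicate 2 of the arrays labelled Myc knockout, limma called 0 genes in either direction, while 2 rose and 0 fell without replicate 1 of those arrays and 0 rose and 1 fell without replicate 3; at an unadjusted p under 0.05, these fits gave 1311 to 1572 genes higher and 1454 to 1688 lower. With an intensity trend in the prior variance 162 genes rose and 208 fell, and among genes at or above the median brightness 204 rose and 345 fell.

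**Figure D1:**
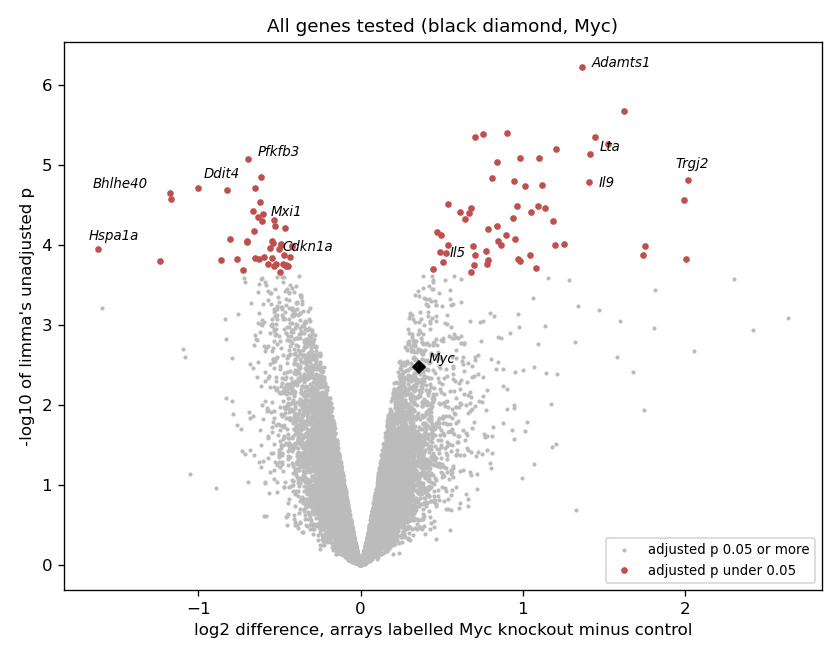
Each point is a gene, with its log2 difference (arrays labelled Myc knockout minus control) on the x axis and the negative log10 of limma's unadjusted p on the y axis. Red points are the 59 genes that rose and the 46 that fell, and the black diamond marks Myc at a log2 difference of 0.36.

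**Figure D2:**
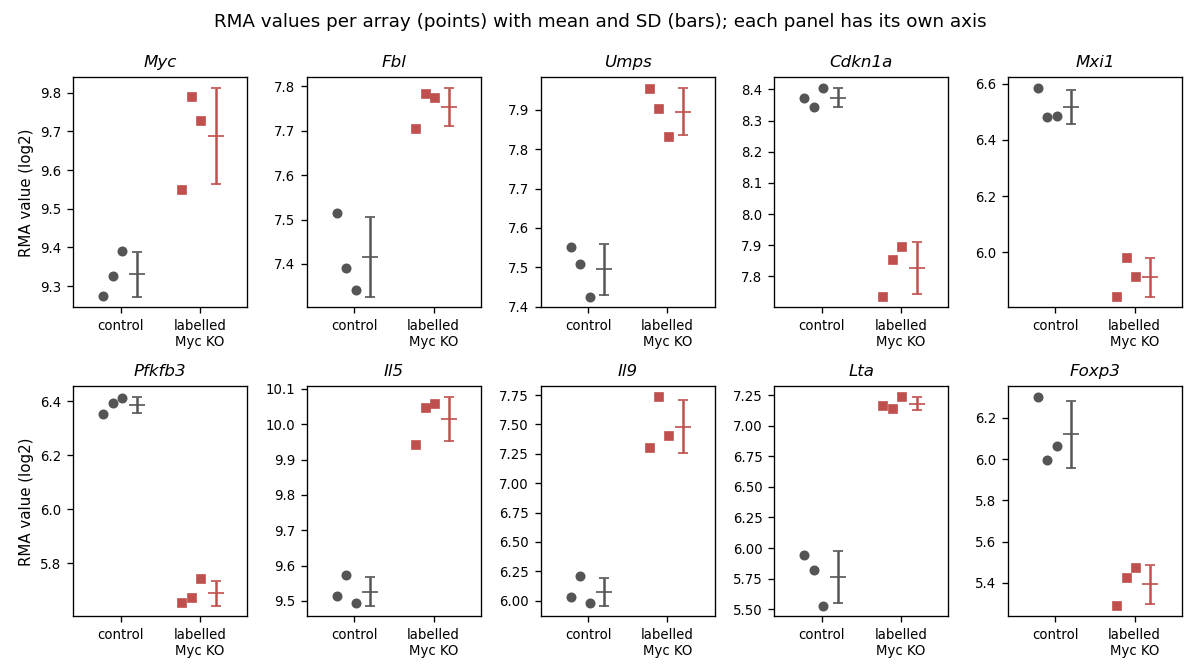
Log2 RMA values of 10 genes are shown per array (points) with the mean and SD (bars) for 3 control arrays and 3 arrays labelled Myc knockout, each panel with its own y axis that does not start at 0. In each panel all 3 arrays of a group lie on the same side of the other group, with Myc between 9.27 and 9.39 in the controls and between 9.55 and 9.79 in the arrays labelled Myc knockout.

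Genes for making ribosomes were shifted upward together in the arrays labelled Myc knockout. Of 40 ribosome biogenesis and nucleolar genes, 37 had a positive log2 difference, and the median was 0.15. Fbl, which encodes the rRNA methyltransferase fibrillarin, was at 7.42 ± 0.089 in controls and 7.75 ± 0.043 in the arrays labelled Myc knockout (log2 difference 0.34 ± 0.067), and Gar1 had a log2 difference of 0.39 ± 0.084. Ncl, the gene of nucleolin, stood at 0.12 ± 0.058. None of the 40 passed over all genes tested and 20 were higher at an unadjusted p under 0.05; adjusted over the list alone, 9 rose and 0 fell. The list passed limma's camera test over the 26 gene lists (adjusted p = 9.65e-10), and it was the only list called that also passed with an estimated correlation (adjusted p = 0.0379).

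Other lists of biosynthesis were mixed. Of 22 nucleotide synthesis genes, 17 had positive differences (median 0.11), 0 passed over all genes and 9 were higher at an unadjusted p under 0.05; 6 rose adjusted over the list alone, among them Umps, an enzyme of pyrimidine synthesis (0.40 ± 0.064), and Rrm2, a ribonucleotide reductase subunit (0.31 ± 0.085). This list passed camera (adjusted p = 0.000276), with adjusted p = 0.122 with an estimated correlation. The 21 aminoacyl-tRNA synthetase genes also passed (median 0.060, camera adjusted p = 0.00936; adjusted p = 0.179 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone and 4 higher at an unadjusted p under 0.05; Tars differed by 0.24 ± 0.063. Translation factors (median 0.064, 24 genes), polyamine synthesis genes (0.11, 10 genes), amino acid transport and one-carbon genes (0.054, 21 genes) and cytosolic ribosomal protein genes (−0.095, 20 genes) did not pass camera, with adjusted p = 0.0802, 0.131, 0.104 and 0.132. No member of these 4 lists passed over all genes; the counts at an unadjusted p under 0.05 were 6, 3, 3 and 0 higher and 0, 0, 1 and 2 lower. Adjusted over the list alone, Mtap and Srm rose among the polyamine genes and Shmt1 and Mthfd1 rose and Aldh1l2 fell among the one-carbon genes, with 0 in the translation factor and ribosomal protein lists. Odc1, the first enzyme of polyamine synthesis, differed by 0.17 ± 0.16, within its spread. Eif2b3 differed by 0.31 ± 0.077 and Rpl14 by −0.57 ± 0.14 without passing. Control levels of Rps16, Rps2 and Rpl3 (1.53, 2.13 and 3.09) were below the array medians, so the ribosomal protein list cannot show a lack of change for them. Without control replicate 1 the ribosomal protein list passed as lower and the amino acid list as higher (adjusted p = 0.0366 and 0.0301), and without control replicate 2 the translation factors passed as higher (adjusted p = 0.0465). The polyamine median ranged from 0.049 without replicate 1 of the arrays labelled Myc knockout to 0.16 without replicate 2 of those arrays.

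Inhibitors of the cell cycle were among the genes that fell. Cdkn1a and Cdkn1b, which encode the CDK inhibitors p21 and p27, fell 1.46-fold (8.37 ± 0.031 to 7.83 ± 0.083) and 1.47-fold in the arrays labelled Myc knockout, as did Ccng2, an atypical cyclin gene (1.75-fold), and Pdcd4, an inhibitor of translation (1.40-fold), with limma's adjusted p between 0.0353 and 0.0361. These 4 fell and 0 rose over all genes among 21 CDK inhibitor and antiproliferative genes; adjusted over the list alone 7 fell and 2, Txnip and Klf6, rose. The list passed camera as lower (median −0.060, adjusted p = 0.00889; adjusted p = 0.264 with an estimated correlation). Of 28 S phase and DNA replication genes, 24 had positive differences (median 0.089, camera adjusted p = 0.000339; adjusted p = 0.203 with an estimated correlation), with 0 past the threshold over all genes, 7 higher at an unadjusted p under 0.05 and Cdc6 (0.34 ± 0.052), Rfc3 and Ccne1 higher adjusted over the list alone; under cyclic loess Cdc6 also passed over all genes (limma's adjusted p = 0.0495). The 27 G2/M and mitosis genes had a median of 0.077 (camera adjusted p = 0.0249; adjusted p = 0.437 with an estimated correlation), with 0 past the threshold either way, 4 higher at an unadjusted p under 0.05 and Kif20a at 0.14 ± 0.053. Without control replicate 3 or replicate 3 of the arrays labelled Myc knockout the G2/M list did not pass (adjusted p = 0.0755 and 0.203), nor did it under median centring (0.0665). The CDK inhibitor list did not pass without replicate 1 of the arrays labelled Myc knockout (adjusted p = 0.0799), and its median was −0.020 without control replicate 1, −0.092 without control replicate 2 and −0.11 without replicate 2 of the arrays labelled Myc knockout.

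Among 19 MYC network genes, the 2 that fell past the threshold over all genes in the arrays labelled Myc knockout encode antagonists of MYC that share its partner MAX. Mxi1 fell 1.52-fold, from 6.52 ± 0.060 to 5.91 ± 0.069, and Mxd4 fell 1.45-fold (limma's adjusted p = 0.0272 and 0.0353). Over all genes 2 fell and 0 rose, and adjusted over the list alone 3 fell, with Mxd1 added. At an unadjusted p under 0.05 in limma, 1 was higher and 5 were lower. The lower ones included Trrap (−0.21 ± 0.066) and Ep400 (−0.19 ± 0.072), which encode partners of MYC and not antagonists. The list passed camera as lower (median −0.069, adjusted p = 0.0317; adjusted p = 0.264 with an estimated correlation). The 21 p53 target genes did not pass (median −0.012, camera adjusted p = 0.608); Cdkn1a fell over all genes, and Cdkn1a, Bbc3 and Ddb2 fell adjusted over the list alone. Without control replicate 1 or 3, or without replicate 1 or 3 of the arrays labelled Myc knockout, the MYC network list did not pass (adjusted p = 0.0786, 0.0780, 0.0614 and 0.0761), with medians of −0.068, −0.040, −0.029 and −0.068, and without replicate 2 of those arrays its median was −0.11. It did not pass under cyclic loess either (median −0.036, adjusted p = 0.124).

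Glycolysis genes were mostly lower in the arrays labelled Myc knockout. Pfkfb3, whose product raises phosphofructokinase activity, fell 1.62-fold, from 6.39 ± 0.031 to 5.69 ± 0.047 (limma's adjusted p = 0.0162). It was the only 1 of 19 measured glycolysis and lactate genes past the threshold over all genes; adjusted over the list alone 9 fell, among them Aldoc, Pfkp and the glucose transporter genes Slc2a3 and Slc2a1, and 1, the lactate transporter gene Slc16a3, rose. The list passed camera (median −0.11, adjusted p = 0.000830; adjusted p = 0.122 with an estimated correlation). Ldha, the lactate dehydrogenase A gene, differed by −0.087 ± 0.053 without passing. Oxidative phosphorylation and TCA cycle genes (29 measured) had a median of −0.0036, a mean of 0.015 and camera adjusted p = 0.870, and cholesterol and fatty acid synthesis genes (19 measured) a median of 0.0039, a mean of −0.011 and camera adjusted p = 0.502; the median differed in sign from the mean and from camera's direction in both. In these 2 lists 0 members passed over all genes or adjusted over the list alone, with 1 and 1 higher and 0 and 2 lower at an unadjusted p under 0.05; Idh3a differed by 0.24 ± 0.063 and Scd1 by −0.27 ± 0.067. Autophagy and lysosome genes passed camera as lower (24 of 27 negative, median −0.089, adjusted p = 0.00103; adjusted p = 0.179 with an estimated correlation), with 0 past the threshold either way, 4 lower at an unadjusted p under 0.05 and Map1lc3a at −0.26 ± 0.069. Without control replicate 2 the glycolysis median was −0.19, and without control replicate 1 the autophagy and lysosome median was −0.046, both still past the threshold.

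Among genes of ILC2 effector molecules, Il5 and Il9 rose and Vegfa fell in the arrays labelled Myc knockout. Il5 rose 1.40-fold, from 9.53 ± 0.041 to 10.01 ± 0.063, and Il9 rose as given above, while Vegfa, the vascular growth factor gene, fell 1.62-fold (limma's adjusted p = 0.0386, 0.0205 and 0.0353). Il13 differed by 0.23 ± 0.095 (control level 11.1) and Il4 by 0.0026 ± 0.12 (control level 6.65), and neither passed. Control levels of Il6 (3.21) and Csf2 (1.79) were below the array medians and, for Csf2, the lower quartiles, so these cannot show a lack of change. Of 23 type 2 cytokine and effector genes, 2 rose and 1 fell over all genes, and 6 rose and 1 fell adjusted over the list alone; the list passed camera (median 0.14, adjusted p = 0.00253; adjusted p = 0.179 with an estimated correlation). Among 24 IL-2 and STAT5 response genes, Lta and Irf4, the latter an activation-induced transcription factor gene (1.72-fold), rose over all genes and Cish also adjusted over the list alone, 3 in total; camera gave adjusted p = 0.000833 (median 0.094; adjusted p = 0.264 with an estimated correlation). Il9r, the IL-9 receptor gene, fell 1.46-fold as the only member past the threshold over all genes among 27 ILC2 identity genes, and adjusted over the list alone Il9r fell and Kit rose. This list passed camera as lower (20 negative, median −0.11, adjusted p = 0.0109; adjusted p = 0.179 with an estimated correlation). Gata3, the transcription factor gene that specifies ILC2s, differed by −0.25 ± 0.066 and did not pass. The call of Il5 was lost under median centring and that of Il9r under cyclic loess, with limma's adjusted p = 0.05005 and 0.0596 at log2 differences of 0.46 and −0.52, against 0.49 and −0.55. Without control replicate 3 the median of the type 2 cytokine list was 0.073, still past the threshold. The 22 interferon response genes did not pass (median −0.058, camera adjusted p = 0.124): 0 passed over all genes, with 1 higher and 4 lower at an unadjusted p under 0.05, and adjusted over the list alone Ifit1 rose and Rsad2, Isg20 and Stat2 fell. The median of this list ranged from −0.041 without control replicate 2 to −0.11 without replicate 2 of the arrays labelled Myc knockout.

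Some markers of other lymphocytes moved beside these cytokine genes in the arrays labelled Myc knockout. Il17a, a cytokine gene of ILC3s and of some T cells, rose from 2.84 ± 0.17 to 3.79 ± 0.14, and Klrk1, which encodes the NK cell receptor NKG2D, rose from 3.08 ± 0.17 to 3.76 ± 0.038 (limma's adjusted p = 0.0353 and 0.0473). Both stayed near the array medians of 3.27 to 3.34. Foxp3, the regulatory T cell transcription factor gene, fell 1.66-fold, from 6.12 ± 0.16 to 5.39 ± 0.095 (adjusted p = 0.0458 in limma). The 13 ILC3 markers (2 rose over all genes and adjusted over the list alone, Lta and Il17a; median 0.066) and the 17 NK cell and ILC1 markers (1 rose over all genes, and Klrk1 and Klrd1 adjusted over the list alone; median 0.10) passed camera, with adjusted p = 0.00289 and 0.0317. With an estimated correlation adjusted p = 0.179 for both. The mean level over members and arrays was 2.78 for the ILC3 list and 3.51 for the NK cell and ILC1 list. Both lie near or below the array medians, so these calls include many dim genes. Lta is also in the IL-2 and STAT5 list, and Ncr1 is in both marker lists. T cell markers (17 genes, median −0.033), B cell markers (12 genes, 0.011), myeloid markers (19 genes, 0.036) and mast cell and basophil markers (14 genes, −0.040) did not pass, with camera adjusted p = 0.486, 0.630, 0.978 and 0.742. The medians of the B cell and myeloid lists were positive and their means negative (−0.067 and −0.020), and camera's direction was lower for B cell and higher for myeloid markers. Over all genes Foxp3 alone passed in these 4 lists, and adjusted over the list alone Foxp3, Ighm and 1 myeloid marker, Itgam, fell; at an unadjusted p under 0.05, 2, 0, 0 and 1 were higher and 3, 1, 1 and 1 lower. Ighm differed by −0.83 ± 0.16, Itgam by −0.63 ± 0.10 and Ms4a2, below the lower quartiles of the arrays, by 0.23 ± 0.063. Without control replicate 3, or without replicate 1 or 2 of the arrays labelled Myc knockout, the NK cell and ILC1 list did not pass (adjusted p = 0.147, 0.0724 and 0.0715), nor did it under cyclic loess (0.0751). The ILC3 median was 0.11 without control replicate 2, 0.12 without control replicate 3 and 0.10 without replicate 2 of the arrays labelled Myc knockout.

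**Figure D3:**
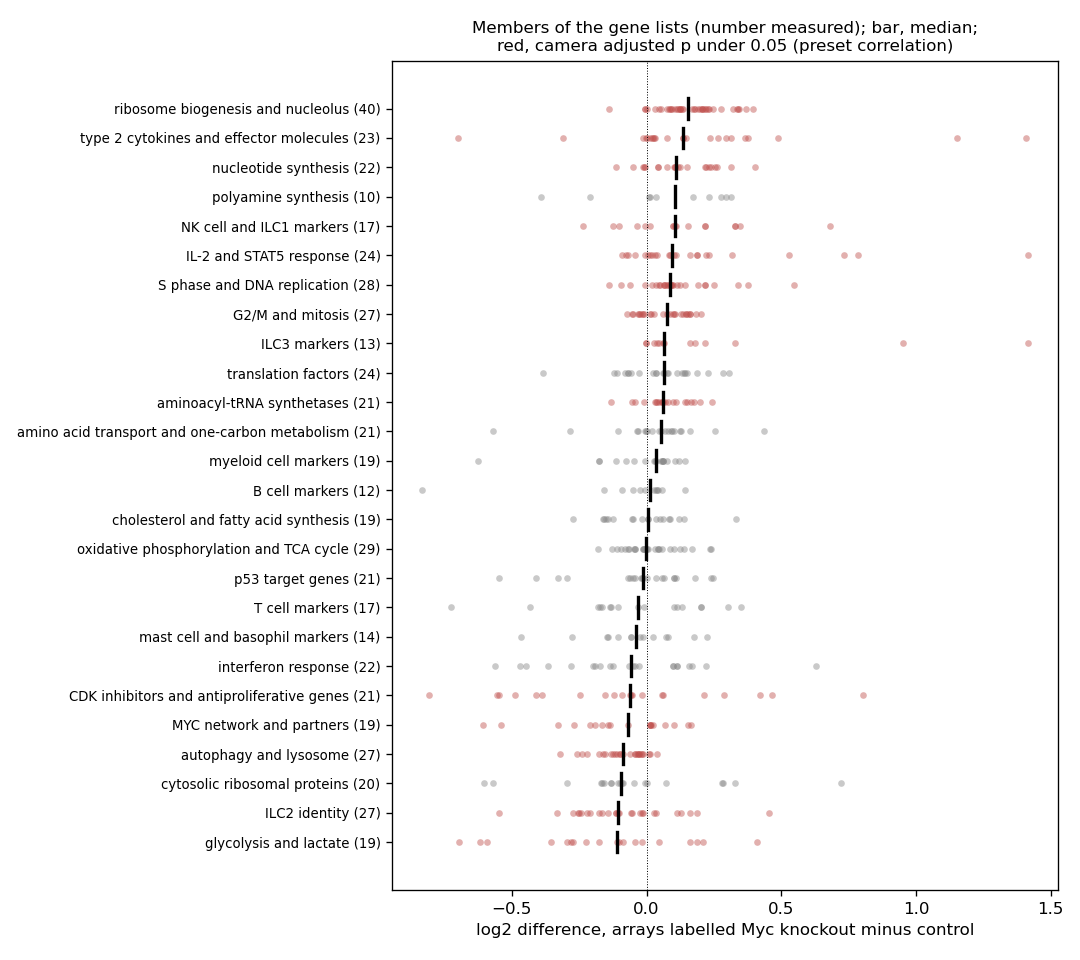
Each row is a gene list with its number of measured genes, each point a member's log2 difference (arrays labelled Myc knockout minus control) and the black bar the median. Red rows are the 14 lists with camera adjusted p under 0.05 at the preset correlation, from a median of 0.15 for ribosome biogenesis to −0.11 for glycolysis.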

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

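The unnamed probe sets were outside the comparison of named genes. When all 25206 probe sets were tested together with limma, 3 unnamed probe sets rose and 4 fell in the arrays labelled Myc knockout (adjusted p under 0.05), with log2 differences between −0.78 and 1.38. They drew attention because they passed the threshold in data that the comparison did not use, and no gene was assigned to them here.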

How the results depend on the processing

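The restriction to protein-coding genes was chosen after the data were seen. The count of genes rested on all 6 arrays: leaving out any 1 array gave 0 to 2 genes higher and 0 to 1 lower, and with a replicate block limma called 0 higher and 0 lower (1486 and 1560 at an unadjusted p under 0.05), which takes degrees of freedom from 6 arrays. The labels give both groups the numbers 1 to 3 without saying that they pair arrays. Deviations from the group means correlated at −0.070, −0.012 and −0.017 between arrays of like number. No control array correlated best with the array labelled Myc knockout of its own number, and the reverse was not examined. The counts were 162 higher and 208 lower with an intensity trend, 204 and 345 among genes at or above the median brightness, 92 and 100 above the lower quartile, where fewer genes were tested, 51 and 24 at 1.5-fold or more, and 0 and 0 at an adjusted p under 0.01, below the smallest adjusted p of 0.0138; protein-coding genes alone gave 42 and 42. Taking the mean of all probe sets of a gene changes nothing, since no gene had more than 1, and the robust prior has no list test. Of 53 named genes besides Myc, 32 passed the threshold, and all 53 had 1 direction in all alternatives run. The groups of nearly all these genes do not overlap, so leaving out or weighting an array could not reverse them. Most other alternatives leave the log2 difference as it is, so the constant direction is little support. Counting each gene in each alternative, the call stayed the same in 543 cases, was lost in 226 and was gained in 18. No list called turned direction in any alternative run. Dim genes near background limit what can be seen on arrays.

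Myc passed only among genes at or above the median brightness (0.358, adjusted p = 0.0487; range over its alternatives 0.0487 to 0.307). Where a list changed its side of the threshold, the cause was not tested, and values are median log2 differences. With the trend, translation factors (0.0637) and amino acid transport (0.0544) passed. Median centring ended the call of G2/M (0.0528). Cyclic loess added translation factors (0.0745) and polyamine synthesis (0.139) and ended the MYC network and partners (−0.0363) and NK cell calls (0.0766). At or above the median brightness translation factors (0.0663), amino acid transport (0.0496) and interferon response (−0.195) passed, and CDK inhibitors (−0.0906), the MYC network (−0.0685) and ILC2 identity (−0.115) did not. Above the lower quartile translation factors (0.0663) passed and the MYC network (−0.0685) did not. The estimated correlation, which widens the test alone and leaves the medians as they are, ended the calls of aminoacyl-tRNA synthetases (0.0597), glycolysis (−0.110), nucleotide synthesis (0.111), S phase (0.0889), G2/M (0.0772), CDK inhibitors (−0.0605), the MYC network (−0.0685), ILC2 identity (−0.107), type 2 cytokines (0.136), IL-2 and STAT5 (0.0937), autophagy (−0.0890), NK cells (0.105) and ILC3 (0.0659). With fry, translation factors (0.0637) and polyamine synthesis (0.105) passed and G2/M (0.0772) did not. On ranks CDK inhibitors (−0.0605), the MYC network (−0.0685) and NK cells (0.105) did not pass. Leaving out 1 array each changed the side of the threshold for 7 lists, whose medians ranged from −0.106 to −0.0221 for ribosomal proteins, 0.0496 to 0.0831 for translation factors, 0.0300 to 0.0790 for amino acid transport, 0.0565 to 0.0861 for G2/M, −0.112 to −0.0200 for CDK inhibitors, −0.111 to −0.0285 for the MYC network and 0.0766 to 0.133 for NK cells. Among lists not called in any alternative, these medians ranged from −0.0195 to 0.0212 for oxidative phosphorylation, −0.0278 to 0.0087 for cholesterol synthesis, −0.0172 to 0.0296 for p53 targets, −0.0909 to −0.0064 for T cell, −0.0517 to 0.0365 for B cell, 0.0164 to 0.0447 for myeloid and −0.0752 to 0.01002 for mast cell markers.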

Other observations

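The tests of exchanged labels, lower MYC activity, genes picked because they were called, culture conditions, RNA size, host transcripts, particle proteins and scaling that depends on intensity, and the lists of hypoxia-responsive genes and of small RNA classes, were chosen after the results were seen; the counts over other splits were not. The tests of exchanged labels and of lower MYC activity first used the ribosome biogenesis list, which is the pattern itself, and the test of RNA size first used all C/D small nucleolar RNAs within the range of the H/ACA lengths (median −0.048); all 3 were redefined after these first outcomes were seen. The tests of scaling first used median centring too, and were reduced to cyclic loess after the outcomes were seen. Centring moves all genes of an array alike. It leaves a list's median relative to all genes unchanged, though it can change the camera p. The criterion for the particle proteins was likewise made to require the estimated correlation, and that for host transcripts to compare their upper quartile with the H/ACA median, after the outcomes were seen. The patterns below were picked after looking at all 105 genes past the threshold, at 10 families of symbols, at chromosome neighbours and at 3 lists added for hypoxia-responsive genes and small nucleolar RNA particle proteins, so each is a hypothesis found on the data that test it. Tests of these added classes and lists were adjusted over the 11 tested, and those of ribosome biogenesis and nucleotide synthesis over the 26 lists fixed earlier. All genes named in this part were chosen after their values were seen. All directions rest on the labels. Myc mRNA, a weak check of them, was higher in the arrays labelled Myc knockout without passing limma's test over all genes.

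T cell receptor gamma segments had positive log2 differences in 15 of 15 measured segments, some of them near 0, such as Trgv1 (0.011 ± 0.080). For 9 segments all values of the arrays labelled Myc knockout lay above all controls, and 5 rose (Trgj1, Trgj2, Trgc1, Trgc2 and Trgv3). The constant region segments Trgc1 and Trgc2 rose 1.95-fold and 1.75-fold, from 8.71 ± 0.16 and 8.33 ± 0.11, while Trgc4, at 11.1 in the controls, differed by a log2 value of 0.14 ± 0.078 and did not pass limma's test. The median of the segments was 0.42 (camera adjusted p = 1.77e-10; adjusted p = 0.110 with an estimated correlation). The segments hold near-identical copies that a probe set can share, and probe sequences were not examined, so the values of single segments are uncertain. Among small RNAs, the 529 microRNA genes had a median of 0.017 (camera adjusted p = 0.335), and Mir142 was the member that rose. The 65 C/D small nucleolar RNAs had a median of −0.056 (camera adjusted p = 0.528). In limma 0 of the 65 passed the threshold, and 5 were higher and 4 lower at an unadjusted p under 0.05.

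Myc mRNA and ribosome biogenesis genes were both higher in the arrays labelled Myc knockout; under cyclic loess the list's median was 0.169 above that of all genes, which argues against the intensity trend that loess removes as the whole cause. An exchange of the labels of the 2 groups may be considered, as may lower MYC activity with the mRNA left in place by indels. Whether MYC activates nucleotide synthesis genes in these cells was not tested. If it does, their list would be higher after an exchange and lower with lower MYC activity. The list was higher, with medians of 0.087 to 0.14 over its 17 alternatives, and it passed in 16 of them. With camera's estimated correlation it did not pass (adjusted p = 0.122, the highest over the alternatives, the lowest being 1.71e-06). The direction was thus the one named for an exchange. The criterion asked for both correlations, so the test decided neither explanation. Other lists pointed different ways. CDK inhibitors were lower (median −0.060, camera adjusted p = 0.00889). S phase, G2/M and aminoacyl-tRNA synthetase genes were higher (medians 0.089, 0.077 and 0.060, camera adjusted p = 0.000339, 0.0249 and 0.00936). If MYC drives growth and division in these cells, which was not tested, these shifts would go with an exchange. Glycolysis genes, also often activated by MYC, were lower (median −0.11, camera adjusted p = 0.000830), which would not. Of these 19 genes, 5 are also among the hypoxia-responsive genes described below, and glycolysis was not tested without them. Ribosomal protein genes had a median of −0.095 but did not pass camera (adjusted p = 0.132). Some were dim, so this list counts for neither side. In the order given, none of these lists passed with an estimated correlation (adjusted p = 0.264, 0.203, 0.437, 0.179, 0.122 and 0.437). Exchanged labels and a response to the genotype cannot be told apart here, because the genotype is known only from the labels.

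Hypoxia-responsive genes were lower in the arrays labelled Myc knockout: of 25 genes, 24 had negative differences and 7 fell (Bhlhe40, Ddit4, Ankrd37, Vegfa, Pfkfb3, Hilpda and Mxi1). Of the 25, 8 are also in lists described before, 5 of them in glycolysis (Pfkfb3, Slc2a1, Pdk1, Ldha and Pgk1), with Mxi1 (MYC network), Vegfa (type 2 effectors) and Ndrg1 (CDK inhibitors). The shifts of these shared genes are not separate patterns. Other members of those lists that fell, such as Cdkn1a, Cdkn1b and Mxd4, are outside the 25. The earlier lists were not tested without the shared genes. Under cyclic loess the list's median was −0.364 relative to all genes, which argues against an intensity trend between arrays as the whole cause. The whole list had a median of −0.381 (camera adjusted p = 8.21e-19; adjusted p = 0.0585 with an estimated correlation), and the 18 members not past the threshold had a median of −0.284, which excludes nothing, because the list was written after several of its members had been seen among the calls. Oxygen or cell density of the cultures could give such a pattern, and the labels give neither, so this and the genotype cannot be told apart.

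H/ACA small nucleolar RNAs, which guide pseudouridylation of RNA, were higher in the arrays labelled Myc knockout, with a median of 0.42 over 34 RNAs, 7 that rose, and camera adjusted p = 5.26e-11 (adjusted p = 0.225 with an estimated correlation). Their 24 host genes, found for 29 of the 34, had a median of −0.050 with quartiles of −0.13 and 0.10. For the hosts as a set, this argues against host RNA levels, as the arrays read them, that are higher by about as much. Transcription of the hosts was not measured, so higher transcription stays open. Dim hosts, such as Rps2 (2.13 in the controls), cannot show a lack of change. Single RNAs were not tested against their own hosts, and Tpt1, the host of Snora31 (1.25), was itself higher by 0.52. Under cyclic loess the H/ACA median relative to all genes was 0.434, against an intensity trend as the whole cause. Recovery of RNA by size may contribute and stays open: the C/D RNAs are shorter (median 68 nt against 121 nt), and only 4 lay between the lower quartile and the maximum of the H/ACA lengths, with a median of −0.068. Across the H/ACA RNAs, which are not independent replicates, length and log2 difference had Pearson's r = 0.403 (permutation p = 0.0177) and Spearman's rho = 0.214 (permutation p = 0.221), and r was 0.232 without the 2 lengths farthest from the median. Higher mRNA of the 7 H/ACA particle proteins (median 0.17), of which 4 are in the ribosome biogenesis list, passed with the preset correlation (camera adjusted p = 0.00147) and not with an estimated one (0.0534 before adjustment, adjusted p = 0.147), so it stays open, as does the genotype, which was not tested separately. The 3 C/D particle proteins had a median of 0.20 (camera adjusted p = 0.0105, and 0.275 with an estimated correlation), while the C/D RNAs had a median of −0.056. In that class, higher particle protein mRNA did not go with higher RNAs.

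Of the 10 splits of the 6 arrays into 3 and 3, 1, the real split, gave as many as 105 genes past the threshold, and the highest of the others gave 0. For gene lists, 1 of the 10 splits, again the real split, gave as many as 14, and the highest of the others gave 6. With 10 splits the share cannot fall below 0.05, so the splits are too few for a test.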
